A study of Drosophila melanogaster and Drosophila simulans and Drosophila yakuba with 12 samples.

How the data were processed

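Small RNA was isolated from whole larvae and prepupae, size-selected, joined to indexed adapters and sequenced, as the labels state. Of the libraries in the deposited tables, 12 in 8 groups belong to this series. Columns of 4 libraries of another series, 8 in all, were not used here.

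Per the file headers and the submitters' processing notes, the authors aligned reads to the miRNA hairpins of miRBase release 15 with Bowtie 0.12.5. The deposited summary table holds expected counts: the reads of each hairpin arm divided by the number of matching loci. The deposited alignment texts hold a whole-number read count for each distinct read sequence and library, with 176 hairpins for D. melanogaster, 136 for D. simulans and 80 for D. yakuba. Neither kind of file is normalised. The genome versions behind the authors' locus coordinates are not given in the sources used here.

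The summary table holds fractions, because a read that matches several loci is divided among them. Reads were therefore summed again from the alignment texts for each mature arm, counting a read on several copies of 1 miRNA once and dividing a read listed for several miRNAs, such as miR-276a-5p and miR-276b-5p, evenly among them. These sums were used throughout. Of 3138 cells of the summary table that could be compared, all but 5 lay within 1 read of the weighted sums (99.84%). Each library was counted on the hairpins of its own species (338, 260 and 140 mature arms, 124 of them shared by all 3 species), and comparisons between species used the shared arms. Totals per library were 1423 to 48209 reads, which is shallow, so that shares carry exact Clopper-Pearson intervals at the 95% level and counts of 0 a floor of 3 counts. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Ratios of reads compare shares of the summed totals, with exact intervals.

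The technical libraries of D. simulans and D. yakuba prepupae came from 1 RNA each and were summed, which left 10 RNA samples. Numbers 1 and 2 of the D. melanogaster male samples go with the library pool. A check of same-pool deviations between larvae and prepupae gave an r of 0.66 over 58 miRNAs, so the pool was tried as a replicate block. The p-values measure the spread between these samples, which the tests share in part over miRNAs. Counts were scaled by TMM, filtered with filterByExpr and tested with the edgeR quasi-likelihood F test, with Benjamini-Hochberg adjustment in each comparison and a threshold of 0.05. The comparisons were stage in D. melanogaster males (a model of 4 group means over 6 libraries), stage over both sexes (terms for stage and sex), stage across species (8 male samples, terms for species and stage), stage by species, species, sex, and stage by sex. Log2 changes are fitted values with the SE from the test statistic. Arm usage was log2 of 5p over 3p reads with a pseudocount of 0.5 for hairpins with 20 reads in every sample, and 5′ end use the logit (natural log of the odds) of reads at the usual start for arms with 50 reads in every sample, both fitted with limma.

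The miRNA lists were the let-7 complex, steroid-linked, K box and Brd box, muscle, nervous system, growth and metabolism, digestive tract and Malpighian tubule, imaginal disc and epithelium, Hox cluster, testis-rich, ovary-rich, early embryo cluster, mirtron and miR-310 cluster miRNAs. They were tested with camera where at least 3 members were measured, at a preset correlation of 0.01 and again with an estimated one, and with fry. The named miRNAs were those called (at most 12 in each direction), the 10 with the smallest p, at most 4 of each list and the 10 with the highest shares. let-7, miR-100, miR-125, miR-34, miR-14, miR-8 and bantam were always named in stage comparisons where tested. miR-100 did not pass the filter. miRNAs named from the alternative fits and the pairs of libraries were chosen after their values were seen. Groups, comparisons, lists, the naming rule and most alternatives were fixed before the data were examined.

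The alternatives were RLE and upper-quartile scaling, DESeq2, no filter, 100 reads in every sample, each library left out in turn, leaving out the 3 miRNAs with the most reads, leaving out miRNAs from several loci or 1 base from another, the summary counts, the replicate block, single pools, and single technical libraries. Alternatives chosen after seeing the data were the index as a term, the 4 male libraries of D. melanogaster alone, the D. melanogaster hairpins for all libraries in the stage, stage by species and arm usage fits, and arm usage over hairpins with reads on both arms in every sample. The fits across species with the label number as a replicate block, or with the index as a term, took the technical libraries of 1 RNA as separate samples. The scaling moved the median log2 change of all tested miRNAs. With TMM it was 0.118 for stage in D. melanogaster males and −0.303 across species, −0.847, −0.281 and −0.192 for D. simulans minus D. melanogaster, D. yakuba minus D. melanogaster and D. simulans minus D. yakuba, and −0.917 for stage by sex. With RLE these were 0.039, −0.033, −0.344, −0.075, 0.176 and −0.333, and with upper-quartile scaling 0.192, 0.337, −0.42, −0.319, 0.41 and −1.12. Over both sexes the median was 0.018, −0.081 and 0.791 under the 3 scalings, and for sex −0.056, 0.029 and 0.264. For the stage by species differences of the same pairs it was 0.424, 0.359 and 0.24 with TMM, 0.596, 0.339 and 0.334 with RLE, and −0.326, −0.461 and 0.227 with upper-quartile scaling.

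Pairs of libraries were compared over miRNAs with a mean of 10 reads, and again 100, with a pseudocount of 0.5. Correlations of library pairs were tested with 100000 permutations of the index, stage or pool labels, and intervals of correlations across miRNAs came from 10000 bootstraps. The fits were tested on simulated data, 20 data sets of about 30 changed miRNAs for each comparison. At the spread of these data edgeR recovered 11%, 47.5% and 89.5% of changes of 4, 16 and 64-fold in D. melanogaster males, 50.3%, 98% and 100% for stage across species, and 0%, 3.5% and 13% for stage by sex. Among the calls 2.3% to 7% were false, and up to 11.9% at a smaller spread (coefficient of variation 0.2). Much of the simulated set was changed, about 30 of 39.6 to 77 miRNAs tested on average. The simulated libraries carried no index or pool effect, so these shares need not hold for the real calls. The tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Coordinates were read from the BDGP6 annotation, which need not be the build used by the authors.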

Results

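Small RNA of whole animals was sequenced in 12 libraries made from 10 total RNA samples of 3 fruit fly species, Drosophila melanogaster (strain Oregon-R), D. simulans and D. yakuba. Larvae were collected 18 h before puparium formation, the hardening of the larval skin that opens metamorphosis, and prepupae within 1 h after it. In D. melanogaster, 2 samples each of male larvae and male prepupae and 1 sample each of female larvae and female prepupae were sequenced. In D. simulans and D. yakuba, 1 sample of male larvae and 1 of male prepupae were sequenced. Each prepupal RNA was made into 2 technical libraries, which differed in index and in pool. Every library carried a 4-nt index joined to the 5′ end of the insert and was run in 1 of 3 pools. Reads on the miRNA arms of the library's own species numbered 29168 and 10113 in D. melanogaster male larvae, 10629 and 9024 in male prepupae, 4721 in the female larva sample and 48209 in the female prepupa sample. They numbered 4762 in D. simulans larvae, 23502 and 5086 in its prepupal libraries, 3731 in D. yakuba larvae, and 21744 and 1423 in its prepupal libraries.

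The 10 miRNAs with the highest mean share held most reads in every library but 1. miR-1-3p, the muscle miRNA of bilaterian animals, held 16.8% of the reads on average, between 0.978% and 47.4% over the 12 libraries. miR-184-3p followed with 14.3% (6.39% to 23.6%), miR-31a-5p with 11.9%, miR-8-3p with 6.93% (0.068% to 30.9%), and miR-263a-5p, a miRNA of sense organ survival, with 6.75%. miR-10-3p, encoded in the Antennapedia complex, held 5.25%, miR-31b-5p 3.70%, miR-282-5p 3.69%, miR-275-3p 2.51%, and miR-33-5p, a miRNA of lipid metabolism, 2.5%. These 10 together held between 39.97% of the reads in female larvae and 86.05% in a D. yakuba prepupal library. The muscle group, miR-1 and miR-133, held 0.979% in a male prepupal library of D. melanogaster and 47.4% in a D. yakuba prepupal library. The let-7 complex, in which let-7, miR-100 and miR-125 are cut from 1 transcript, held at most 0.147% of the reads in larval libraries and between 0.235% and 1.32% in prepupal libraries. Testis-rich miRNAs held 0.202% to 0.565% in the 4 male libraries of D. melanogaster, against 0.0635% (3 reads) in the female larva and 0.0539% in the female prepupa sample. Ovary-rich miRNAs gave at most 2 reads in a library, and early embryo cluster miRNAs held 0.0332% to 0.854%. Mirtrons, whose hairpins are spliced introns, held at most 0.170%, the miR-310 cluster at most 0.256%, and Hox cluster miRNAs 0.499% to 13.5%.

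The first comparison asked which miRNAs changed level between late larvae and prepupae of D. melanogaster males. let-7-5p, a timing miRNA whose cluster is induced by the steroid hormone ecdysone, rose by 7.06 ± 1.72 on the log2 scale (SE, n = 2 and 2), from 1 and 1 reads to 53 and 77 reads, a ratio of 129.9 with a counting interval of 35.3 to 1084. miR-8-3p, a miRNA of insulin signalling and body growth, rose by 4.05 ± 1.13, from 177 and 253 reads to 444 and 2791. miR-999-3p rose by 6.85 ± 1.75, from 0 and 3 reads to 5 and 166, a ratio of 113.9 with a counting interval of 38.3 to 558, and of 6.16 (1.20 to 39.7) without male prepupa replicate 2. miR-282-3p rose by 4.62 ± 1.49, from 7 reads in larvae to 88 in prepupae. miR-7-5p, known for photoreceptor differentiation and for targets in Notch signalling, fell by 4.94 ± 1.65, from 1635 and 150 reads to 20 and 3. miR-5-3p, of the K box family, fell from 114 and 6 reads in larvae to 0 in prepupae, at least 20.01-fold lower with a floor of 3 counts over the group, and at least 3.89-fold without male larva replicate 1.

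Of 70 miRNAs tested with edgeR, these 6 passed an adjusted p of 0.05, 4 higher and 2 lower, and 14 had an unadjusted p under 0.05. The adjusted p was 0.00483 for let-7-5p and miR-999-3p, 0.0105 for miR-8-3p, and 0.0387 for the other 3, and each prepupal library lay on the same side of both larval libraries. DESeq2 called 5 miRNAs, let-7-5p, miR-8-3p, miR-282-3p, miR-7-5p and miR-34-5p (−4.21 ± 1.10, adjusted p = 0.00282), and did not call miR-999-3p or miR-5-3p. In edgeR miR-34-5p, a miRNA of ageing and of ecdysone and juvenile hormone response, had a log2 change of −4.29 ± 1.51 (3126 and 191 reads in larvae, 55 and 10 in prepupae, adjusted p = 0.0518). miR-2b-5p had −4.48 ± 1.78 and the shared reads of miR-276a-5p and miR-276b-5p 3.51 ± 1.41, both with an adjusted p of 0.0992. miR-125-3p, from the let-7 transcript, had 3.68 ± 1.55 (27 reads in prepupae against 3, a ratio of 17.99 with a counting interval of 5.54 to 92.7, adjusted p = 0.110). The growth miRNA bantam-3p had 1.09 ± 1.31, bantam-5p −0.23 ± 1.80, the cell death and fat metabolism miRNA miR-14 1.84 ± 1.32 for its 3p arm and 0.18 ± 1.30 for its 5p arm, and miR-8-5p −0.99 ± 1.32. With the pool as a replicate block, the 4 male libraries gave 20 calls of 50 tested and, without the replicate block, 10. The blocked calls held miR-34-5p (−4.06 ± 0.31, adjusted p = 1.81e-16), miR-7-5p (−4.94 ± 0.26), miR-33-5p (−2.51 ± 0.22), miR-10-3p (−2.47 ± 0.49), miR-2b-5p (−4.49 ± 0.89) and miR-276a-5p (3.56 ± 0.76). With terms for pool and stage, 4 libraries leave little spread to measure for 1 miRNA. The blocked SE and p thus rest largely on the spread shared over miRNAs. miR-8-3p was called in the 4 libraries without the replicate block (3.98 ± 1.47, adjusted p = 0.0400) and not with it (3.44 ± 2.06, adjusted p = 0.201).

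Among the steroid-linked miRNAs, 8 of 12 tested were higher in male prepupae. let-7-5p and miR-8-3p passed over all miRNAs, and 5 members passed when adjusted over the list alone (median 0.64). Of the arms on the K box and Brd box list, 7 of 9 were lower, with 1 call over all miRNAs and 1 adjusted over the list alone. Their median of −1.08 stayed the same with miR-5-3p at its bound of −4.32. Of 16 growth and metabolism miRNAs 9 were higher (1 call, 2 adjusted over the list alone), of 10 imaginal disc miRNAs 5 (1 call higher and 1 lower, 2 adjusted over the list alone), of 6 nervous system miRNAs 4 (1 call, lower, 1 adjusted over the list alone), of 5 digestive tract miRNAs 3 and of 3 testis-rich miRNAs 1, without a call. No list passed the camera test, which compares a list with the other miRNAs. The smallest adjusted p was 0.203, for the K box and Brd box list, and 0.659 with an estimated correlation. For the nervous system, digestive tract and testis-rich lists, the median and the test differed in sign.

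In D. melanogaster males, the stage could not be told apart from the index: both larval libraries carried ACTG and both prepupal libraries TGAC. The TGAC library of D. yakuba prepupae also held 29.5% miR-8-3p, against 3.001% in the CGAT library of the same RNA. For let-7-5p these 2 libraries held 0.563% (8 reads) and 0.0552% (12 reads). The ACTG library of D. simulans prepupae held 2.24% miR-7-5p, against 0.0851% in the GACT library of the same RNA, and 0.531% let-7-5p, against 0.506%. Pool changed together with index between the libraries of each RNA. No call was made without male larva replicate 1, without male prepupa replicate 1 or without female larva replicate 1, and miR-7-5p passed in none of the 6 fits that left out a library. miR-8-3p passed in 1 of the 6, that without the female prepupa sample, and had 1.59 ± 2.21 (adjusted p = 0.821) without male prepupa replicate 2 and an adjusted p of 0.0530 without male larva replicate 2. let-7-5p and miR-282-3p passed in 3 of 6, and miR-999-3p and miR-5-3p in 2 of the 5 in which they were tested.

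**Figure D1:**
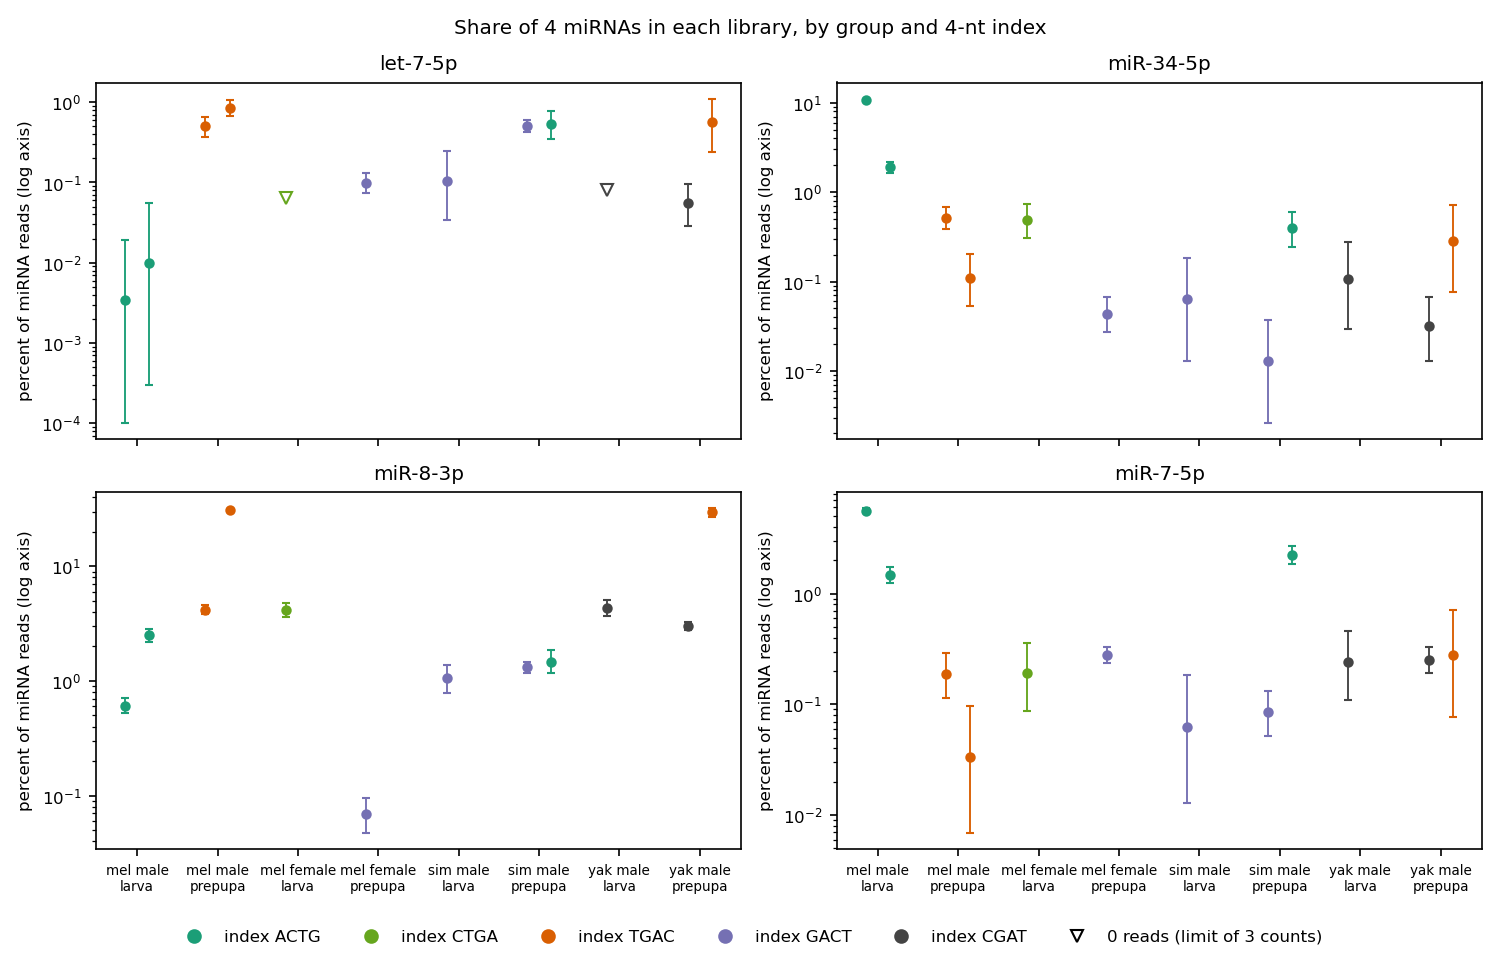
Percent of miRNA reads (log axis) held by let-7-5p, miR-34-5p, miR-8-3p and miR-7-5p in each of the 12 libraries, coloured by index. Bars are exact 95% counting intervals and open triangles mark 0 reads at the limit of 3 counts. miR-8-3p stands at 4.18% and 30.9% in male prepupae of D. melanogaster and at 29.5% in the D. yakuba library with the same index.

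Adding the 2 female libraries asked which stage changes hold over both sexes of D. melanogaster. The stages shared no index here either, so that stage and index could not be told apart. let-7-5p rose by 7.16 ± 1.85 (n = 3 and 3, adjusted p = 0.00948), and each prepupal library lay above every larval library, with 178 reads in prepupae against 2 in larvae, a ratio of 57.7 (15.7 to 480.0). miR-34-5p fell by 3.89 ± 1.19 (adjusted p = 0.0363), and in normalised counts each prepupal library lay below every larval library. It held 10.7% and 1.89% of the reads in male larvae and 0.487% in female larvae, against 0.518%, 0.111% and 0.0436% in the prepupal libraries. Libraries of 1 RNA also differed in miR-34-5p. D. simulans prepupae held 0.393% with ACTG, the index of the male larvae, and 0.0128% (3 reads) with GACT, that of the female prepupa sample. D. yakuba prepupae held 0.281% (4 reads) with TGAC, the index of the male prepupae, and 0.0322% (7 reads) with CGAT. miR-282-3p had 3.70 ± 1.503, miR-7-5p −3.38 ± 1.56, miR-958-3p −3.98 ± 1.52, miR-10-3p −1.74 ± 1.02 and miR-263a-5p 1.67 ± 1.00, with adjusted p from 0.166 to 0.657. The others were miR-8-3p with 2.43 ± 1.69, bantam-3p with 1.74 ± 1.26, miR-276a-5p with 2.12 ± 1.61, miR-14-5p with 1.70 ± 1.55, miR-14-3p with 0.86 ± 1.45 and miR-8-5p with −1.07 ± 1.04. Of 48 miRNAs, edgeR called 2 and DESeq2 5, and the replicate block left 1 call, let-7-5p (6.94 ± 1.18, adjusted p = 0.0330). Steroid-linked miRNAs were higher in 7 of 10 cases (1 call higher and 1 lower, 2 adjusted over the list alone, median 1.28, camera adjusted p = 0.759). All 6 tested arms of the K box and Brd box list were lower without a call, miR-5-5p and miR-79-3p (−0.0035 ± 2.27) included. Growth and metabolism miRNAs were higher in 8 of 13 cases (1 call, lower, 1 adjusted over the list alone), digestive tract miRNAs in 2 of 4 (1 adjusted over the list alone), and nervous system and imaginal disc miRNAs in 3 of 4 and 5 of 8, with a positive median and a negative test direction. No call was made without male larva replicate 1 or without male prepupa replicate 2, 1 without male prepupa replicate 1, 6 without female larva replicate 1 and 9 without female prepupa replicate 1. let-7-5p passed in 4 of these 6 fits and miR-34-5p in 2.

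The third comparison asked which stage changes the males of all 3 species share, in 8 samples with a term for species. let-7-5p was called, with a rise of 4.90 ± 1.07 (n = 4 and 4, adjusted p = 0.0214). It gave 296 reads in prepupae against 7 in larvae, a ratio of 28.3 (13.6 to 71.0). In each species every prepupal RNA lay above every larval RNA of that species, although the values overlapped between species. For D. yakuba the order rests on few reads: 0 larval reads allow up to 0.099%, and the prepupal libraries held 0.0552% (CGAT) and 0.563% (TGAC, 8 reads). The other miRNAs with small p did not pass: the axial patterning miRNA miR-10-3p had −1.88 ± 0.67, miR-33-5p −1.93 ± 0.71 and miR-92a-3p 1.98 ± 0.73, all with an adjusted p of 0.165. miR-34-5p had −2.85 ± 1.14 (adjusted p = 0.196), miR-276a-5p and miR-276b-5p 1.79 ± 0.83, miR-283-5p −1.36 ± 0.71, miR-8-3p 1.84 ± 1.01 and miR-11-3p −1.04 ± 0.58. miR-8-5p had −0.72 ± 0.58, bantam-3p 0.57 ± 0.73 and miR-14-5p −0.31 ± 0.65, which was 0.34 with upper-quartile scaling. Of 35 miRNAs, 5 had an unadjusted p under 0.05, and DESeq2 called 2, let-7-5p and miR-92a-3p. Steroid-linked miRNAs were higher in 5 of 8 cases (1 call, 1 adjusted over the list alone, camera adjusted p = 0.652), K box and Brd box in 1 of 5, nervous system in 1 of 3, growth and metabolism in 7 of 13 and imaginal disc in 2 of 6, without a call. The fit gave 0 calls without D. melanogaster male larva replicate 1 or male prepupa replicate 1, without D. simulans prepupa replicate 1 and without the D. yakuba larva library, 4 without the D. simulans larva library, and 2 without D. melanogaster male prepupa replicate 2 or D. simulans prepupa replicate 2. let-7-5p itself passed in 5 of the 9 fits without a library in which it was tested, and without D. melanogaster male larva replicate 2 it had 4.41 ± 1.23 (adjusted p = 0.0595), where the 1 call was miR-125-3p. The call was also lost with the label number as a replicate block, where let-7-5p had 4.57 ± 1.02 (adjusted p = 0.0560). It was lost too with the library index as a term, an alternative chosen after seeing the data, where let-7-5p had 3.16 ± 1.36 (adjusted p = 0.560). Both fits took the technical libraries of 1 RNA as separate samples, so their SE and p do not rest on independent RNA samples alone.

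Within 1 index, larvae and prepupae can be compared in D. simulans (GACT) and D. yakuba (CGAT), with 1 RNA sample per species and stage. Both larval libraries came from pool SDY4 and both prepupal libraries from pool SDY3, so that stage and pool cannot be told apart there. No RNA sample was repeated within a species and stage. The SE and p thus rest on how far the stage changes of the species differ and on the spread shared over miRNAs. In this comparison let-7-5p rose by 2.34 ± 0.59 (n = 2 and 2, adjusted p = 0.00416), miR-125-3p rose by 4.32 ± 0.64 (adjusted p = 1.96e-06) and miR-10-3p fell by 1.19 ± 0.27 (adjusted p = 0.00137), 3 calls of 39 miRNAs in edgeR. let-7-5p went from 5 to 119 reads in D. simulans, a ratio of 4.82 (2.01 to 15.1), and from 0 to 12 reads in D. yakuba, where the share of 0.0552% lies under the 0.0806% that 0 larval reads allow. miR-125-3p went from 2 to 179 reads in D. simulans, a ratio of 18.1 (4.95 to 151), and from 0 to 34 in D. yakuba, at least 1.94-fold higher against a floor of 3 counts in the library. miR-8-3p had −0.17 ± 0.25, miR-7-5p 0.19 ± 0.54, bantam-3p −0.066 ± 0.70, bantam-5p 0.94 ± 0.72, miR-14-3p 0.65 ± 1.03, miR-14-5p −0.56 ± 0.44 and miR-8-5p 0.0796, none of which passed. Of the steroid-linked miRNAs 7 of 10 were higher (2 calls, 2 adjusted over the list alone, camera adjusted p = 0.0709, 0.868 with an estimated correlation).

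Over 43 miRNAs, the mean stage change of D. melanogaster males had a Pearson r of 0.574 (95% bootstrap interval 0.363 to 0.789, Spearman rho 0.708) with the difference between the TGAC library of D. yakuba prepupae and the ACTG library of D. simulans prepupae, in which index and species change together. Without mir-305 and mir-281, whose reads the D. simulans hairpins miss in part, this r was 0.707 (0.535 to 0.860) over 40 miRNAs. With the stage change measured within 1 index it had an r of 0.601 (0.325 to 0.776, rho 0.475). Both are correlations across miRNAs, which are not independent replicates. Pairs of libraries of different species that shared an index had a mean r of 0.777 over 6 pairs, against 0.636 over 39 other pairs (difference 0.141, one-sided permutation p = 0.00064, adjusted p = 0.00192 over 3 tests). Sharing the stage gave a difference of 0.069 (permutation p = 0.0173, adjusted p = 0.026) and sharing the pool 0.059 (permutation p = 0.146, adjusted p = 0.146).

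**Figure D2:**
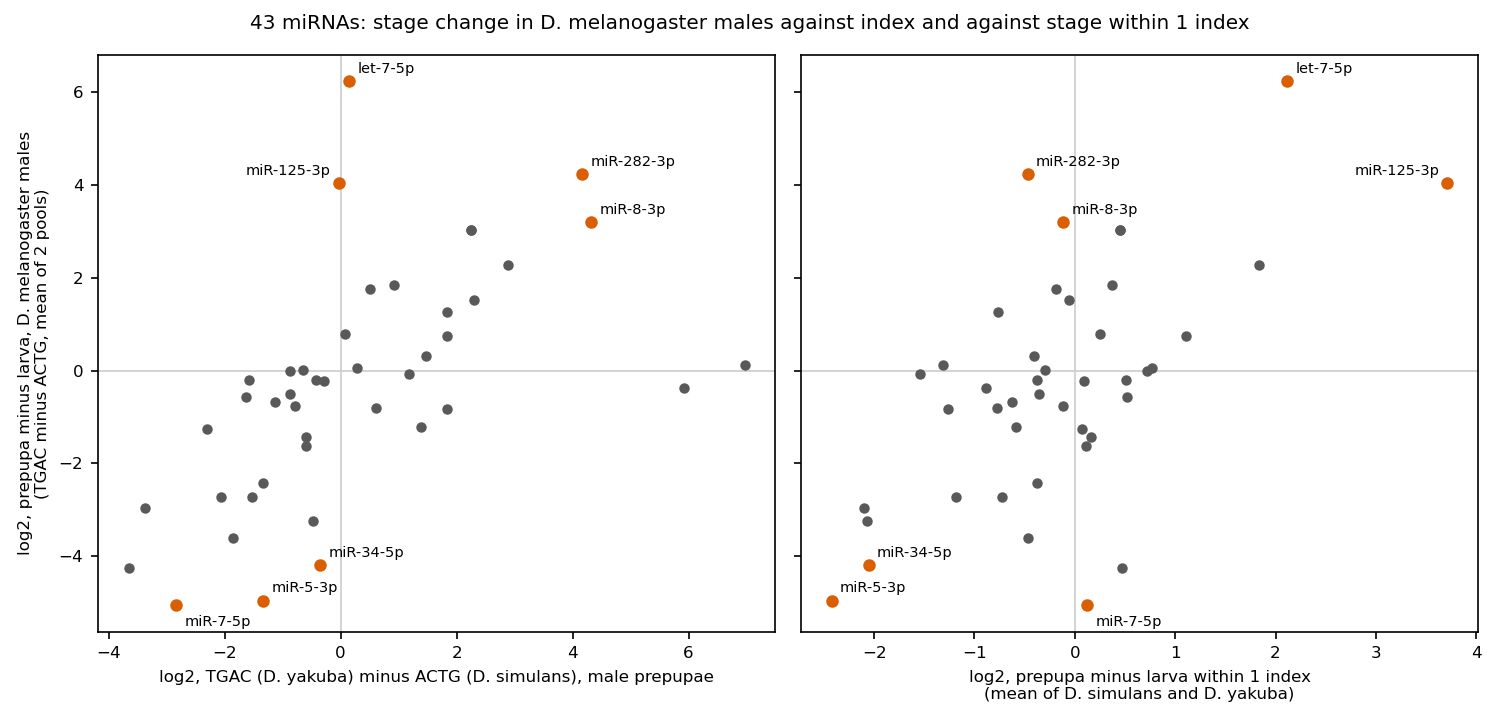
Each point is 1 of 43 miRNAs: the vertical axis gives the log2 change from larva to prepupa in D. melanogaster males (mean of 2 pools), the left horizontal axis the log2 difference between the TGAC library of D. yakuba and the ACTG library of D. simulans prepupae, and the right one the log2 stage change within 1 index. let-7-5p and miR-125-3p lie high in both panels and near 0 on the left axis, while miR-8-3p and miR-7-5p go the same way on the left axis, where index and species change together and r is 0.574. The left axis does not show index differences within 1 RNA: in D. yakuba prepupae let-7-5p held 0.563% with TGAC and 0.0552% with CGAT.

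Whether the stage change itself differs between species was tested with a term for stage by species in the 8 male samples. No miRNA of 51 passed the joint edgeR test, 2 had an unadjusted p under 0.05, and DESeq2 called 0. miR-7-5p had the smallest p (adjusted p = 0.117), with a stage change higher by 7.74 ± 2.37 in D. simulans than in D. melanogaster (adjusted p = 0.0772) and by 4.92 ± 2.15 in D. yakuba than in D. melanogaster (adjusted p = 0.998). In D. simulans minus D. melanogaster edgeR called 0 and 6 had an unadjusted p under 0.05, and DESeq2 called 1, miR-7-5p (7.91 ± 2.17, adjusted p = 0.0140). let-7-5p had −4.69 ± 2.19, miR-34-5p 4.55 ± 2.28, miR-282-3p −5.33 ± 2.63, miR-8-3p −3.50 ± 2.12 and miR-2b-5p 11.38 ± 4.33, with adjusted p from 0.254 to 0.647. For D. yakuba minus D. melanogaster edgeR and DESeq2 called 0 and 1 had an unadjusted p under 0.05. There let-7-5p had −0.17 ± 0.88, miR-8-3p −3.78 ± 2.12, miR-34-5p 3.02 ± 2.24, miR-14-3p −2.60 ± 2.15 and bantam-3p 0.14 ± 2.01. D. yakuba larvae gave 0 reads of let-7-5p, and D. simulans larvae 0 of miR-2b-5p and miR-14-3p. A stage change from 0 reads has no upper bound, so the fitted differences and SE of these miRNAs do not measure its size. For D. simulans minus D. yakuba edgeR and DESeq2 called 0 and 0 had an unadjusted p under 0.05, with the smallest p for miR-14-3p (7.23 ± 4.54, adjusted p = 1.00).

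All 8 K box and Brd box miRNAs had a higher stage change in D. simulans than in D. melanogaster (median 1.89, camera adjusted p = 0.0502, 0.597 with an estimated correlation), and all 8 a higher one in D. yakuba (median 1.46, adjusted p = 0.0908, 0.823 with an estimated correlation). Both differences share the D. melanogaster libraries, and the 8 members are arms, with both arms of a hairpin counted where tested. The steroid-linked list was higher for 6 of 12 members in both, the Hox cluster for 2 of 3, the imaginal disc list for 4 of 8 and the let-7 complex for 1 of 3. The nervous system list was higher for 1 of 3 in both, with a negative median and a positive test direction, and 1 member passed adjusted over the list alone in D. simulans, as did 1 imaginal disc member. The growth and metabolism list was higher for 8 and 10 of 17, in D. yakuba with a positive median and a negative test direction. Only 1 larval and 1 prepupal RNA sample stood behind D. simulans and behind D. yakuba. The SE of these differences thus hold the spread between D. melanogaster samples and none within the other species. In data simulated at this size the test found 41%, 35% and 33% of 64-fold differences for the 3 pairs of species.

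Species differences that hold over both stages were tested in the same 8 male samples. miR-11-3p, which lies in the E2f1 gene and tempers its cell death function, was higher by 2.61 ± 0.63 in D. simulans than in D. melanogaster (254 reads against 85, adjusted p = 0.0303). miR-281-5p was lower in D. simulans, with −6.75 ± 1.16 against D. melanogaster (4 reads against 736, adjusted p = 0.00462) and −6.36 ± 1.18 against D. yakuba (4 against 176, adjusted p = 0.00711). miR-305-5p had no read in D. simulans, against 748 in D. melanogaster and 723 in D. yakuba, at least 141-fold and at least 299-fold lower with a floor of 3 counts over the group (adjusted p = 0.00462 and 0.00423). On the D. melanogaster hairpins, however, the D. simulans libraries gave 273 reads of miR-305-5p and 255 of miR-281-5p. miR-92b-3p was lower in D. simulans than in D. yakuba with −3.004 ± 0.80 (98 reads against 294, adjusted p = 0.0435), and miR-14-5p was higher by 4.81 ± 1.22, with 121 reads against 3, a ratio of 32.5 (10.9 to 160; adjusted p = 0.0412). With the technical libraries summed, every D. simulans RNA lay on the same side of every RNA of the other species for these calls. Taken alone, the ACTG library of the D. simulans prepupal RNA did not do so for 3 of them. It held 0.138% miR-11-3p, against 0.838% in the GACT library of the same RNA and 0.189% and 0.158% in the ACTG libraries of D. melanogaster larvae. For miR-92b-3p it held 1.24%, against 0.136% with GACT and 0.725% to 1.48% in D. yakuba, and for miR-14-5p 0.0983% (5 reads), against 0.383% with GACT and 0.211% (3 reads) in the TGAC library of D. yakuba.

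For D. simulans minus D. melanogaster edgeR called 3 of 44 miRNAs (1 higher, 2 lower) and DESeq2 6. The Wingless-pathway miRNA miR-315-5p had 2.77 ± 0.77 (adjusted p = 0.0555), miR-34-5p −4.29 ± 1.41, miR-92b-3p −2.13 ± 0.73, miR-2b-3p −2.32 ± 0.83, miR-10-5p −3.69 ± 1.54, miR-14-5p 1.83 ± 0.79 and miR-92a-3p −2.27 ± 1.03. For D. yakuba minus D. melanogaster edgeR called 0 of 44, 9 had an unadjusted p under 0.05, and DESeq2 called 4, miR-1-3p, miR-283-5p, miR-315-5p and miR-34-5p. In edgeR the muscle miRNA miR-1-3p had 2.97 ± 0.80 and miR-315-5p 2.68 ± 0.78, both with an adjusted p of 0.145. miR-283-5p had 2.24 ± 0.73, miR-34-5p −4.11 ± 1.39, miR-14-5p −2.99 ± 1.12 and miR-iab-4-5p, a Hox cluster miRNA, 3.09 ± 1.19. miR-282-3p had −4.10 ± 1.70, miR-305-3p −2.76 ± 1.16, the insulin-linked miR-278-5p 2.43 ± 1.02 and bantam-3p −2.25 ± 1.05. Between D. simulans and D. yakuba edgeR called 4 of 44 (1 higher, 3 lower) and DESeq2 4. miR-92a-3p had −3.52 ± 1.20, miR-33-5p 2.03 ± 0.90, miR-iab-4-5p −3.35 ± 1.49, let-7-5p 3.84 ± 1.72, miR-283-5p −1.79 ± 0.89 and miR-284-5p 2.69 ± 1.40.

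By list, the members higher in D. simulans than in D. melanogaster were 4 of 10 steroid-linked, 1 of 6 K box and Brd box (1 call, 1 adjusted over the list alone), 1 of 3 nervous system, 5 of 16 growth and metabolism (1 call, lower, 1 adjusted over the list alone), 2 of 6 imaginal disc and 0 of 3 Hox cluster miRNAs. In D. yakuba against D. melanogaster they were 5 of 10, 2 of 6, 1 of 3, 8 of 16, 4 of 6 and 2 of 3, without a call. In D. simulans against D. yakuba they were 5 of 10 (1 call, 1 adjusted over the list alone), 2 of 6, 1 of 3, 7 of 16 (1 call higher and 1 lower, 2 adjusted over the list alone), 3 of 6 and 0 of 3. No list passed camera, where the smallest adjusted p of the 3 pairs was 0.934, 0.741 and 0.808. Median and test differed in sign for the steroid-linked and nervous system lists of the first pair, the nervous system list of the second, and the first 4 lists and the imaginal disc list of the third. With the index as a term, an alternative chosen after seeing the data, no species call was left. That fit took the technical libraries of 1 RNA as separate samples, so its SE do not rest on independent RNA samples alone. In D. simulans minus D. melanogaster miR-11-3p then had 0.17 ± 1.23, miR-281-5p −9.22 ± 2.59 and miR-305-5p −9.37 ± 3.18, and in D. simulans minus D. yakuba miR-14-5p had −0.26 ± 2.02 and miR-92b-3p −0.56 ± 1.43. On the D. melanogaster hairpins none of these calls was left either, but miR-11-3p (2.93 ± 0.84, adjusted p = 0.0603), miR-14-5p (5.005 ± 1.41, adjusted p = 0.138) and miR-92b-3p (−2.50 ± 1.04, adjusted p = 0.267) had differences about as large, while those of miR-281-5p (−0.55 and −0.13) and miR-305-5p (−0.31 and −1.95) shrank. There 1 other call was made for D. simulans minus D. melanogaster, miR-305-3p (−7.55 ± 1.67, adjusted p = 0.0151), of which the D. simulans libraries gave 70 reads on their own hairpins and 1 on these. D. simulans minus D. melanogaster had 6 calls without D. melanogaster male prepupa replicate 2 or without D. simulans prepupa replicate 2 and 2 without D. simulans prepupa replicate 1 or the D. simulans larva library. D. yakuba minus D. melanogaster had 1 without D. melanogaster male prepupa replicate 1 or the D. simulans larva library, and D. simulans minus D. yakuba had 2 without prepupa replicate 1 or the larva library of D. simulans or of D. yakuba. Over the 10 fits without a library, miR-11-3p passed in 8 against D. melanogaster, and miR-14-5p in 6 and miR-92b-3p in 2 against D. yakuba.

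Males and females of D. melanogaster were compared over both stages, with 4 and 2 libraries. miR-958-3p was lower in males with −4.54 ± 1.32 (adjusted p = 0.0442), with 62, 1, 0 and 0 reads in males and 109 and 69 in females. As a share of reads, male larva replicate 1 (62 of 29168) lay above the female prepupa sample (69 of 48209). miR-279-3p, a miRNA of sensory neurons, had −3.46 ± 1.495 (57 reads in males against 492 in females), miR-34-5p 3.07 ± 1.40, miR-10-5p −3.04 ± 1.42, miR-305-5p −2.48 ± 1.24, miR-958-5p −2.19 ± 1.19, miR-282-5p 2.60 ± 1.46, miR-33-5p −2.63 ± 1.55, miR-281-3p −2.50 ± 1.53 and miR-996-3p −2.06 ± 1.29, with adjusted p of 0.477 and above. Of 58 miRNAs, edgeR and DESeq2 called 1, and 5 had an unadjusted p under 0.05 in edgeR. With the replicate block edgeR called 0, 2 had an unadjusted p under 0.05, and 0 were called without any one of the libraries other than the female prepupa library. Each sex had its own index at each stage, so that sex and index could not be told apart. Of the digestive tract miRNAs 1 of 5 was higher in males (1 call, lower, 1 adjusted over the list alone, median −2.19, camera adjusted p = 0.136), of the steroid-linked 7 of 11, of K box and Brd box 4 of 8, of nervous system 4 of 5, of growth and metabolism 7 of 14, with median −0.70 and a positive test direction, and of imaginal disc miRNAs 5 of 8.

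The stage change was also compared between the sexes, with 1 female library per stage. miR-8-3p was called: its stage change was higher by 9.28 ± 2.13 in males than in females (adjusted p = 0.00181), since it was higher in both male prepupal libraries than in both male larval libraries and stood at 4.17% in the female larva and 0.0685% in the female prepupa sample (ratio 0.016, 0.011 to 0.024). let-7-5p had a difference of −0.38 ± 1.34, which was 0.0188 with upper-quartile scaling. The female larva sample gave 0 reads of let-7-5p and of miR-14-5p, so the female stage changes of both have no upper bound. miR-34-5p had −1.52 ± 2.38, miR-7-5p −6.19 ± 2.73, miR-14-5p −10.56 ± 3.74, miR-33-5p −5.45 ± 2.32, miR-282-5p −4.62 ± 2.26, miR-12-5p 5.90 ± 2.67, miR-996-5p 6.28 ± 2.46, miR-316-3p 5.999 ± 2.88, miR-9b-5p −8.01 ± 4.01 and miR-284-5p −5.06 ± 2.67, with adjusted p of 0.189 and above. edgeR called 1 of 70 miRNAs and DESeq2 2, miR-8-3p and miR-12-5p. The 4 groups carried 4 different indexes, and the call was lost without male larva replicate 1 and without male prepupa replicate 1 or 2, while 3 calls were made without male larva replicate 2. Of the steroid-linked miRNAs 4 of 12 were higher (1 call, 2 adjusted over the list alone), of growth and metabolism 6 of 16 (1 call, 2 adjusted over the list alone), both with median −0.96 and a positive test direction. Of imaginal disc miRNAs 3 of 10 (1 call, 1 adjusted over the list alone), of K box and Brd box 3 of 9, of nervous system 2 of 6, of digestive tract 1 of 5 and of testis-rich miRNAs 1 of 3 were higher, the last 2 with a negative median and a positive test direction.

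The balance of the 5p and 3p arms was compared over 12 hairpins of the 8 male samples with limma. No hairpin passed the test for stage or for any of the 3 species pairs, with 0 hairpins at an unadjusted p under 0.05 for stage, 1 for D. simulans minus D. melanogaster, 1 for D. yakuba minus D. melanogaster and 0 for D. simulans minus D. yakuba. The smallest p by stage was that of miR-8, with −2.29 ± 1.15 for the log2 ratio of 5p to 3p reads (adjusted p = 0.615). For D. yakuba minus D. melanogaster it was miR-10 with −3.27 ± 1.40 (adjusted p = 0.288), and for the other 2 pairs miR-33, whose 3p arm gave 5 reads over all male samples and 0 in D. simulans and D. yakuba, so that its value follows the depth of the 5p arm. Of the 12 hairpins, 4 had no read of 1 arm in any male sample and 9 had none in at least 1 sample, and for these the test says little. Over the 3 hairpins with reads on both arms in every sample, miR-8, miR-10 and miR-276a, an alternative chosen after seeing the data, limma called 0 by stage and for each pair, with 1 at an unadjusted p under 0.05, miR-10 in D. yakuba minus D. melanogaster (adjusted p = 0.0897). miR-8 was called by stage without D. yakuba prepupa replicate 1, a fit in which D. yakuba larvae carried CGAT and its prepupae TGAC. Without the D. simulans larva library, miR-305, whose 5p reads the D. simulans hairpins miss, was called in each species pair.

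The 5′ end fixes the seed of a miRNA, so the share of reads at the usual start was compared over 8 arms. By stage limma called 0, with 0 at an unadjusted p under 0.05. D. simulans had a lower share than D. melanogaster for miR-275-3p (−3.77 ± 0.73 on the logit scale, adjusted p = 9.16e-05), miR-184-3p (−3.31), miR-1-3p (−2.38) and miR-31a-5p (−2.37, adjusted p = 0.00531), 4 calls, and a lower share than D. yakuba for miR-184-3p (−4.63 ± 0.84, adjusted p = 3.52e-05), miR-275-3p (−2.81), miR-1-3p (−2.62) and miR-8-3p (−2.21, adjusted p = 0.0254), 4 calls. D. yakuba minus D. melanogaster gave 0 calls and 0 at an unadjusted p under 0.05. The share for miR-184-3p was 98.5% to 99.96% in D. melanogaster, 99.9% and 100% in D. yakuba, and 89.8% in prepupae and 90.9% in larvae of D. simulans. All reads of D. simulans larvae and most of D. simulans prepupae came from GACT libraries, which no other male library carried. In the ACTG library of the same D. simulans RNA, 0 of 1954 reads of the 4 arms started 1 base inside, which allows a share of up to 0.189%, against 6.02% in the GACT library. By stage 3 arms were called without D. simulans prepupa replicate 1, a fit in which D. simulans larvae carried GACT and its prepupae ACTG. The D. simulans calls against D. melanogaster and D. yakuba fell to 2 and 2 without D. melanogaster male larva replicate 1. They fell to 2 and 1 without D. simulans prepupa replicate 1. Against D. yakuba they fell to 1 without D. yakuba prepupa replicate 1 or the D. yakuba larva library.

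Pairs of libraries gave the spread behind these comparisons, as the SD of log2 ratios over miRNAs with a mean of 10 reads. It was 2.01 between the technical libraries of D. simulans prepupae and 1.59 between those of D. yakuba prepupae, where counting alone gives 0.653 and 0.793. These libraries differed both in index and in pool. Between stages within 1 index it was 1.07 in D. simulans and 0.853 in D. yakuba. Between the D. melanogaster male larval RNAs it was 1.83, between the male prepupal RNAs 2.01, and between stages with different indexes 2.53 and 2.39. In the genome build BDGP6, mir-let7 lies at 18472034 to 18472111 on chromosome arm 2L in an exon of the let-7 complex transcript, mir-34 at 10100936 to 10101034 on 3R, mir-8 at 16831432 to 16831518 on 2R, mir-282 at 3251022 to 3251118 on 3L and mir-5 at 19661158 to 19661226 on 2R, all in exons of long noncoding RNAs. mir-7 lies at 20606067 to 20606154 on 2R in an intron of HnRNP-K, and mir-999 at 21798227 to 21798331 on 3R in an intron of CASK. mir-11 lies at 21622497 to 21622571 on 3R in an intron of E2f1, mir-281-1 at 12170373 to 12170462 on 2R in an intron of Oda, and mir-305 at 7425972 to 7426044 on 2L. mir-958 lies at 22669289 to 22669380 on 3L, mir-92b at 25651398 to 25651497 on 3R, and mir-14 at 9553762 to 9553824 on 2R.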

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

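All tests of explanations below were chosen after the results were seen, while the comparison of the technical libraries and the fit within 1 index were planned.

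The stage change of miR-8-3p differed between the sexes of D. melanogaster by 9.28 ± 2.13 on the log2 scale (male minus female), by the test of the difference itself. Each female stage had 1 library, so that the SE comes from the male libraries. In males it stood at 0.607% and 2.502% in larvae and 4.18% and 30.9% in prepupae, and in females at 4.17% in larvae and 0.0685% in prepupae. The 4 groups carried 4 different indexes, and no test here separates sex from index. In prepupae miR-8-3p was lower by 5.91 in the female library (GACT) than in the male library of the same pool (TGAC), and by 4.49 in the GACT library of D. simulans than in the TGAC library of D. yakuba. Untemplated U or A at the 3′ end of reads, outside the comparisons above, made up between 1.19% of the reads in a D. melanogaster male larval library and 2.54% in a D. yakuba prepupal library, and lay above the limit of a count of 0 in 12 of 12 libraries.

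The first pattern weighed is the stage changes of D. melanogaster males, where stage goes with index. The explanation that the 4-nt index shifts the levels of many miRNAs found the value it needs: library pairs of different species that share an index had a mean correlation higher by 0.141 than the others, beyond permuted labels. As the whole cause of the let-7-5p change the index is argued against, since let-7-5p rose by 2.34 ± 0.59 between stages within 1 index. That change is smaller than the one in D. melanogaster, goes with the library pool and was resolved by counting in D. simulans alone. Its SE comes from 1 RNA sample per species and stage, so it holds no spread between RNA samples of a species. An index part of the let-7-5p change stays open. Libraries of 1 D. yakuba RNA held 0.563% (0.243% to 1.11%) with TGAC and 0.0552% (0.0285% to 0.0965%) with CGAT. Those of 1 D. simulans RNA held 0.531% with ACTG and 0.506% with GACT. For miR-8-3p and miR-7-5p an index cause found the values it needs but is not shown, and a biological stage change is not excluded. Libraries of 1 RNA differed 9.84-fold (8.68 to 11.1) for miR-8-3p between TGAC and CGAT and 26.3-fold (16.3 to 44.8) for miR-7-5p between ACTG and GACT. The libraries of 1 RNA also came from different pools (SDY3 and SDY4), so index and pool change together in these folds. Within 1 index, where stage goes with pool, the stage change was −0.17 ± 0.25 for miR-8-3p and 0.19 ± 0.54 for miR-7-5p. Whether the index is the cause of the miR-999-3p, miR-282-3p and miR-5-3p changes cannot be told apart from stage, because the ACTG and TGAC libraries of the other species held at most 4 reads of each.

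The second pattern is the lower share of reads at the usual 5′ end in D. simulans. A property of D. simulans prepupae is argued against: 6.02% of the reads of the 4 arms started 1 base inside in the GACT library (5.65% to 6.41%), against 0 of 1954 in the ACTG library of the same RNA, with an upper limit of 0.189%. A GACT index that lacks its last base may be the cause. On arms that begin with U, at least 1.74% of reads were 1 base short in each GACT library, the D. melanogaster female prepupa library included. On the other arms of these libraries the share was at most 0.392%. The CGAT index of D. yakuba also ends in T and showed no such excess. Its prepupal library held 0.159% on arms that begin with U and 0.192% on the others, and its larval library 0.2% and 0.248%. Reads 1 base short would keep a base of the insert in the place of the index. The test could have failed in the D. melanogaster female prepupa library.

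The third pattern is the lack of miR-305-5p reads in D. simulans. The libraries gave 273 reads on the D. melanogaster hairpin, 0.819% of their reads, against 1.27% in the male libraries of D. melanogaster and 2.69% in D. yakuba, and 70 reads of the 3p arm of the D. simulans hairpin. RNA of D. melanogaster in the libraries is argued against by the 3p arm, with 1 read where at least 34.3 would go with the 5p reads at the ratio of any D. melanogaster library (highest Fisher's exact p = 3.15e-07). RNA of D. yakuba as the source, and with it an absence of miR-305-5p from D. simulans, cannot be told apart from reads of D. simulans, because the ratio differs between the D. yakuba libraries: over their sum 9.8 reads would go with the 5p reads (Fisher's exact p = 0.00345), and at the lowest ratio 2.2 would (highest Fisher's exact p = 0.529). A difference between the miRBase hairpin of D. simulans and the RNA may account for it: the most frequent read was AUUGUACUUCAUCAGGUGC with 110 reads, and the hairpin has AUUGUACUUCAUCAGUGC. miR-281-5p gave 4 reads on the D. simulans hairpins and 255 on those of D. melanogaster.

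Other splits of the samples were counted for the groups of at least 3. For stage over both sexes of D. melanogaster the 10 splits are too few for a share under 0.05, with 2 calls for the real split, reached by 1 split, itself, and at most 1 for the others. For stage across species 3 of 34 splits gave as many calls, with 1 call for the real split and 7 for the highest other, and 1 further split could not be fitted. The 2 splits with 7 calls put the D. melanogaster larvae together with both samples of D. simulans or of D. yakuba. With a term for species they compare the D. melanogaster larvae with the prepupae, as the real split does, so the count decides nothing about chance. The splits with as many samples of each species on either side number 12, too few for a share under 0.05, with at most 0 calls for the others. For arm usage and 5′ end use by stage the real split gave 0 calls, so that 34 of 34 splits had to be as high, which decides nothing, and the others gave at most 2 and 0.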

How the results depend on the processing

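The tests chosen after the result was seen were the index as a term, the 4 male libraries of D. melanogaster without a replicate block, the D. melanogaster hairpins in the stage, stage by species and arm usage fits, and reads on both arms in every sample for arm usage. The other settings were planned. For the named miRNAs, 2396 values under other settings kept their direction and their side of the threshold, 82 passed where they had not, 118 no longer passed, and 44 changed direction. Of the counts and spreads, 260 stayed within 1.5 times or within their error and 109 moved. let-7-5p in D. melanogaster males stayed between 6.43 and 7.79 and passed in 11 of 15 settings, and over both sexes it stayed between 6.28 and 7.87 (10 of 13). Across species it stayed between 2.34 and 6.84 (15 of 21). miR-8-3p stayed between 1.59 and 5.45 (8 of 15), miR-999-3p between 5.58 and 11.02 (7 of 12), miR-282-3p between 4.08 and 5.21 (10 of 15), miR-5-3p between −9.10 and −6.61 (7 of 12) and miR-7-5p between −6.16 and −3.50 (7 of 15). miR-34-5p over both sexes stayed between −4.27 and −2.68 (5 of 14) and miR-958-3p between the sexes passed in 3 of 15. The depth of 1423 reads in the smallest library limits what could be detected. Unless said otherwise, the cause of a change below was not tested. Stage by species could not be fitted without the D. simulans or the D. yakuba larva library (except for the pair of the other species), and stage by sex could not be fitted without a female library.

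For stage in D. melanogaster males (6 calls) there was 1 call with 100 reads in every sample and 0 without multi-locus and near-identical miRNAs, where fewer miRNAs were tested. There were 20 with the pool as a replicate block (miR-8-3p not among them), 10 in the same 4 male libraries with no replicate block (miR-999-3p and miR-5-3p were not tested in either, since they did not pass the filter), and 0 to 7 with a library left out. For both sexes (2 calls) there was 1 call each with RLE scaling, upper-quartile scaling, 100 reads in every sample and the replicate block. There were 0 with no filter and without multi-locus and near-identical miRNAs, 5 with DESeq2, and 0 to 9 with a library left out. For stage across species (1 call) there were 2 with DESeq2, 2 with no filter and 3 in D. simulans and D. yakuba within 1 index. There were 0 with 100 reads in every sample, without multi-locus and near-identical miRNAs, with the label number as a replicate block and with the library index as a term, and 0 to 4 with a library left out.

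For stage by species (0 calls) there was 1 call each with no filter, without multi-locus and near-identical miRNAs and with the pool-matched prepupal library only. For its D. simulans minus D. melanogaster part (0 calls) there was 1 each with DESeq2, no filter, without the 3 miRNAs with the most reads and without multi-locus and near-identical miRNAs, and 2 with the pool-matched prepupal library only. For species, D. simulans minus D. melanogaster (3 calls), there were 6 with DESeq2, 6 with no filter, 6 with the technical libraries of pool SDY3 only and 5 without the 3 miRNAs with the most reads. There was 1 without multi-locus and near-identical miRNAs, 1 on the D. melanogaster hairpins (miR-305-3p, not among the 3), 0 with 100 reads in every sample, 0 with the library index as a term, and 2 to 6 with a library left out. On the D. melanogaster hairpins reads of miR-305-5p and miR-281-5p that the D. simulans hairpins miss are counted, while those of miR-305-3p fall from 70 to 1. For D. yakuba minus D. melanogaster (0 calls) there was 1 with upper-quartile scaling, 4 with DESeq2, 2 with no filter, 4 with pool SDY3 only, and 0 to 1 with a library left out. In D. simulans minus D. yakuba (4 calls) there were 0 with 100 reads in every sample, 1 without multi-locus and near-identical miRNAs, 2 with pool SDY4 only, 0 on the D. melanogaster hairpins, 0 with the library index as a term, and 2 to 4 with a library left out.

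For sex (1 call) there were 0 with upper-quartile scaling, no filter, 100 reads in every sample, without the 3 miRNAs with the most reads, without multi-locus and near-identical miRNAs, with the replicate block and in pool SDY1 only, and 0 to 1 with a library left out. For stage by sex (1 call) there were 2 with DESeq2, 0 with 100 reads in every sample, 0 without multi-locus and near-identical miRNAs, and 0 to 3 with a library left out. For arm usage (0 calls) there were 0 to 1 with a library left out, by stage and in each of the 3 species pairs, and 1 on the D. melanogaster hairpins for D. simulans and for D. yakuba minus D. melanogaster. For 5′ end use by stage (0 calls) there were 0 to 3 with a library left out. For D. simulans minus D. melanogaster (4 calls) there were 2 with 200 reads in every sample and 2 to 5 with a library left out, and for D. simulans minus D. yakuba (4 calls) 1 with 200 reads and 1 to 5 with a library left out. With 200 reads only 2 arms were tested. Of the lists, fry called 1 for sex, the steroid-linked miRNAs (adjusted p = 0.00488), where camera called 0.

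With a mean of 100 reads in place of 10, where fewer miRNAs remain and counting error is smaller, the SD of log2 ratios was 1.24 and 1.72 between the technical libraries of D. simulans and of D. yakuba, 1.32 and 1.92 between the male larval and the male prepupal RNAs of D. melanogaster, and 0.448 and 0.565 between stages within 1 index in D. simulans and D. yakuba. It was 1.97 and 1.87 between the D. melanogaster stages in pools SDY1 and SDY3, 0.952 for D. simulans prepupa and D. melanogaster larva with ACTG, and 0.576 for D. yakuba and D. melanogaster prepupae with TGAC.

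Directions that reversed with a library left out are given as ranges. In D. melanogaster males they were −2.83 to 4.62 for miR-14-3p, −0.33 to 0.41 for miR-14-5p and −0.68 to 0.88 for bantam-5p. Over both sexes they were −0.75 to 4.01 for miR-8-3p and −2.15 to 2.04 for miR-14-3p, and across species −0.59 to 0.23 for miR-14-5p. For D. yakuba minus D. melanogaster in stage by species the range was −5.29 to 2.32 for miR-14-3p. For sex it was −4.39 to 1.18 for miR-33-5p. For stage by sex the ranges were −1.30 to 5.81 for miR-14-3p, −2.19 to 0.41 for miR-34-5p, −1.01 to 0.24 for let-7-5p and −0.52 to 0.0458 for miR-8-5p.

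Under other settings, miR-14-5p in D. melanogaster males was −0.20 with no filter, −0.22 without the 3 miRNAs with the most reads and −0.29 without multi-locus and near-identical miRNAs. Across species miR-14-5p was 0.34 with upper-quartile scaling, 0.0705 without the 3 miRNAs with the most reads, 0.55 without multi-locus and near-identical miRNAs, 0.0669 on the D. melanogaster hairpins and 0.18 with the library index as a term. miR-8-5p across species was 0.0069 without multi-locus and near-identical miRNAs, 0.0796 within 1 index and 0.45 with the library index as a term, and within 1 index miR-8-3p was −0.17 and bantam-3p −0.066. In stage by species miR-305-3p was 0.56 on the D. melanogaster hairpins for D. simulans minus D. melanogaster. Between D. simulans and D. yakuba, miR-7-5p was −0.29 and miR-92b-3p −0.20 with the index-matched library, and miR-275-5p 1.93 with the pool-matched one. With the library index as a term, the species differences were 0.23 for miR-92b-3p in D. simulans minus D. melanogaster, 0.67 for miR-14-5p and 0.11 for bantam-3p in D. yakuba minus D. melanogaster, and −0.26 for miR-14-5p and 0.16 for miR-283-5p in D. simulans minus D. yakuba. miR-283-5p was 0.0695 there with pool SDY4 only. In stage by sex let-7-5p was 0.0188 with upper-quartile scaling and 2.46 with DESeq2, and miR-8-5p was 0.16 with RLE scaling, 0.16 with DESeq2 and 0.15 with 100 reads in every sample.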

Other observations

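No test was run on the values in this part, which were chosen after they were seen.

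Of 66 miRNAs with reads in all 3 species, 61 had the same first 10 bases in each. The 5′ bases of let-7-5p were UGAGGUAGUA in D. melanogaster, D. simulans and D. yakuba, those of miR-1-3p UGGAAUGUAA, those of miR-10-3p CAAAUUCGGU and those of the neuronal miRNA miR-124-3p UAAGGCACGC.

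Of the reads with an untemplated U or A, U made up 75.9% in D. melanogaster female larvae, 69.1% in D. yakuba larvae, and 42.1% in D. simulans larvae. In the technical libraries of D. yakuba prepupae it made up 67.9% and 62.2%, and in those of D. simulans prepupae 47.99% and 42.9%.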
